A study of Euphorbia esula with 12 samples.

How the data were processed

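Poly(A) RNA from crown buds of leafy spurge was sequenced in 12 libraries, 4 biological replicates in each of 3 dormancy states, per the labels. Strand-specific libraries were made with a directional kit and sequenced in pairs on an Illumina instrument, per the labels' protocols. The deposited table gives, for each contig of a de novo style assembly (569227 contigs in 223732 assembly genes), an annotation and expected counts per contig and per gene; the submitters' processing notes name RSEM, and its version and the assembler are not given in the sources used here. RSEM's expected counts share reads between similar contigs by estimation, so near-identical copies of this polyploid species, gene families and fragments of 1 gene in several assembly genes are uncertain as separate genes. The authors' deposited table also holds posterior probabilities of differential expression, between 0 and 1, for each comparison; the tool that made them is not given in the sources used here.

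No genome was used here. Gene names are those of the best Arabidopsis match in the deposited annotation or of its top protein match, taking for each assembly gene the match that carried most estimated reads; 8576 genes had contigs with more than 1 Arabidopsis match. A name is therefore a similarity and not an established identity, and several assembly genes can carry the same name.

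Expected counts per gene were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the 3 groups, which left 19394 genes holding at least 98.2% of each library's counts. Libraries were scaled by trimmed mean of M-values (TMM), and CPM values use that scaling. All 12 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with the group as the only term, and 3 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. Standard errors are the fold change divided by the square root of F. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts between replicates of a state differed by more than sampling noise (chi-square per degree of freedom 1.27 to 5.81), so no library was counted as a copy of another, and the biological coefficient of variation was 8.5%.

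Before the data were examined, 31 lists of 541 Arabidopsis identifiers and 6 lists of annotation words were fixed, including markers of xylem, phloem, epidermis and periderm as tissues a bud sample could hold. A gene was on a list when its chosen match was. Lists with at least 3 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation; members were also adjusted over the list alone. Members with no read in a group, set to a bound of 3 counts, moved no list median. The genes named were also chosen by a rule fixed then: per contrast the 5 largest rises and 5 largest falls among called genes with a named protein match, a mean log2 CPM of at least 2 and no overlap between the groups, 1 gene per match; the 2 members with the smallest p of each list with a call; and a fixed set (SVP, AGL24, FT, BRC1, NCED3, CYP707A1, CCA1, LHY, CBF, COR47 or ERD10, galactinol synthase, CYCD3, DRM1, EPSPS). Since this would name too many genes, list members were named for the 10 lists with the smallest set p in each comparison and for the lists too small to test. That number was chosen after the values were seen, under the part of the rule that lets lists be summarised.

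A fold against a group with no reads is a bound computed against 3 counts over the group, and with 1 to 3 counts an exact binomial (Clopper-Pearson) interval at 95% is given for the ratio; both cover counting error only, since reads carry no molecular identifiers. With 3181407 to 4087266 counts per library, a CPM of 1 is 3 to 4 reads. In simulated counts with the real means, dispersions and library sizes, and 200 genes changed in 1 state, the endodormant against paradormant test on 18680 genes called 53.8% of genes changed 1.5-fold, 87.3% changed 2-fold and 100% changed 4-fold. For ecodormant against endodormant (18740 genes) these were 54.0%, 80.0% and 100%, and for ecodormant against paradormant (18738 genes) 62.7%, 89.6% and 100%. False calls made up 6.5%, 3.5% and 4.8% of the calls. A further set of genes was raised 1.5-fold in the same simulations. Few genes changed there, against 9496 to 12486 called in the data, so these shares need not hold for the real tests.

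Alternatives fixed before the data were examined were DESeq2, relative log expression factors, library size only, no filter or a filter of 1 CPM in 4 libraries, only the 2 groups compared, the replicate number as a block, each library left out in turn, isoforms, plant matches only and a 2-fold minimum. For the lists they were an estimated correlation, the block, library size only and 1 gene per Arabidopsis identifier. The alternative pseudocount planned for normalised values had no use with counts.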

Results

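Crown buds of leafy spurge (Euphorbia esula), the buds at the base of the stem from which this perennial weed regrows, were profiled by poly(A) RNA sequencing in 3 dormancy states with 4 biological replicates each. Paradormant buds, whose growth is held back by signals from other parts of the plant, came from plants kept at 27 C with 16 h of light. Endodormant buds, held back by signals within the bud, came from plants taken over 12 weeks down to 10 C and 8 h of light. Ecodormant buds, held back by the environment alone, came from plants given a further 8 weeks at 7 C and 8 h of light. No library received glyphosate. The total of estimated counts per library was 3846070 ± 316583 in paradormant (SD, n = 4), 3660575 ± 186271 in endodormant and 3556392 ± 275379 in ecodormant buds. Over all 12 libraries it ranged from 3181407 to 4087266. Of 94283 assembly genes with reads, 19394 had enough counts to be tested, and 16589 of these had an Arabidopsis match, which gives the gene names used here.

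Libraries of 1 state resembled each other more than libraries of other states. Across genes, which are not independent replicates, Pearson's r of log2 CPM, counts scaled to library size, was at least 0.9716 within a state. It was between 0.8152 and 0.8393 for paradormant against ecodormant libraries. The first principal component held 65.2% of the variance and ordered the states from paradormant through endodormant to ecodormant, and the second, with 18.0%, set the endodormant libraries apart.

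**Figure D1:**
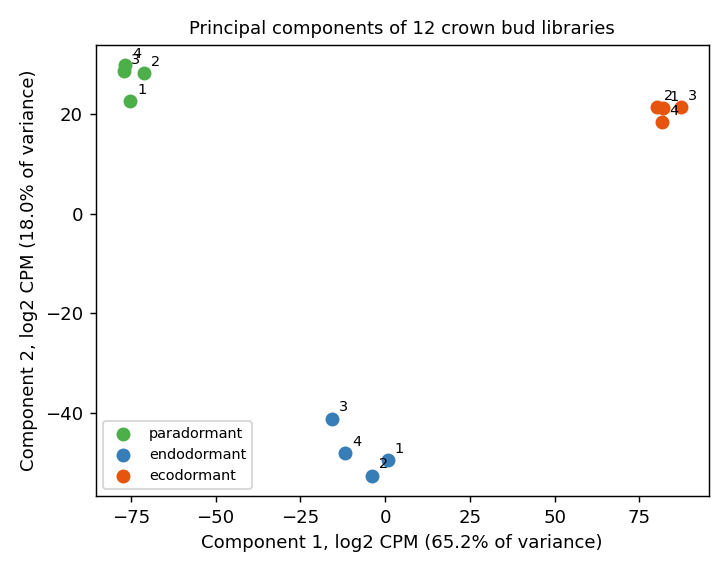
Each point is 1 library, labelled with its replicate number and coloured by dormancy state, on the first and second principal components of log2 CPM (65.2% and 18.0% of the variance). The 4 libraries of each state lie together, with the endodormant libraries between the others on the first component and apart on the second.

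The first comparison asked what changed as buds passed from paradormancy to endodormancy. Genes of photosynthesis, cytosolic ribosomal proteins, the circadian clock and cold response rose as groups, and those of flavonoid synthesis, suberin, flowering, ethylene and jasmonate fell. Only the flowering and ethylene calls held with an estimated correlation (adjusted p = 0.0427 for each), and the other 7 did not (adjusted p = 0.0544 to 0.300). The gene matched to DAM2, a dormancy-associated MADS-box gene of the SVP clade (comp101885_c0), rose from 1.96 ± 0.964 CPM (SD, n = 4) to 28.1 ± 6.38 CPM, a log2 fold change of 3.84 (SE 0.22, adjusted p = 1.1e-12 in edgeR). The more abundant SVP-matched gene (comp110466_c0) rose from 108 ± 7.16 to 185 ± 9.70 CPM (log2 fold change 0.77, SE 0.07). The gene for a cold-response transcription factor of the CBF class (comp116939_c0, protein match CBF1 and Arabidopsis match CBF4) rose from 7.36 ± 1.65 to 103 ± 15.9 CPM (log2 fold change 3.80, SE 0.15, adjusted p = 1e-15 in edgeR).

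Photosynthesis genes rose as a group: of 39 measured members, 37 rose, 1 fell and 1 did not pass the test, with a median log2 fold change of 1.4. Counts were the same adjusted over the list alone. The gene for the small subunit of Rubisco, the carbon-fixing enzyme (comp100017_c0), went from 60.6 ± 10.5 to 460 ± 13.4 CPM (log2 fold change 2.93, SE 0.10). The Calvin cycle enzyme sedoheptulose-1,7-bisphosphatase (comp120381_c0) went from 1.71 ± 0.840 to 34.9 ± 3.69 CPM (log2 fold change 4.31, SE 0.20). The set test gave an adjusted p of 7.06e-17 with the preset correlation, and an adjusted p = 0.195 with an estimated correlation, so this call was lost. Cytosolic ribosomal proteins also rose, with 77 of 99 members higher and 3 lower (79 and 3 adjusted over the list alone) and a median of 0.49. Their adjusted p was 1.13e-13, and the adjusted p = 0.300 with an estimated correlation. Ribosomal proteins S19 (comp112186_c0) and L3 (comp120339_c0) rose by 1.04 (SE 0.07) and 0.98 (SE 0.07) on the log2 scale.

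Of 28 cold and dehydration response genes, 13 rose and 6 fell (set test adjusted p = 0.0143, and adjusted p = 0.300 with an estimated correlation), with the same counts adjusted over the list alone. The genes with the smallest p on this list were both matched to alcohol dehydrogenase, the last enzyme of ethanol fermentation: comp123564_c0 rose from 24.3 ± 4.03 to 518 ± 96.0 CPM and comp121333_c1 from 26.2 ± 3.72 to 571 ± 147 CPM. The more abundant of 2 tested genes matched to COR47 or ERD10, a dehydrin matched to ERD10 (comp116004_c0), rose from 246 ± 52.2 to 1610 ± 136 CPM (log2 fold change 2.72, SE 0.11). Of 21 circadian clock genes, 12 rose and 4 fell (12 and 5 adjusted over the list alone; set test adjusted p = 0.0319, and adjusted p = 0.188 with an estimated correlation). The blue-light receptor FKF1 (comp119728_c0) rose by 2.68 (SE 0.16) and the clock repressor PRR5 (comp118278_c2) by 2.90 (SE 0.19) on the log2 scale, while the LHY-matched gene (comp133357_c0) rose by 0.41 (SE 0.09). All libraries were harvested at about the same clock time of day, under 16 h of light for paradormant and 8 h for endodormant and ecodormant plants.

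Phenylpropanoid and flavonoid genes fell, with 22 of 31 members lower and 2 higher, the same adjusted over the list alone, and a median of -0.76. The gene with the Arabidopsis match flavanone 3-hydroxylase (comp118275_c0, protein match gibberellin 20-oxidase 1) fell from 880 ± 79.9 to 302 ± 25.4 CPM (log2 fold change -1.54, SE 0.09). That with the Arabidopsis match anthocyanidin reductase (comp127805_c0, protein match HC toxin reductase) fell from 140 ± 16.7 to 43.2 ± 5.37 CPM. The set test adjusted p was 1.98e-06, and the adjusted p = 0.0544 with an estimated correlation. All 5 suberin and periderm markers fell (adjusted p = 0.00189, and adjusted p = 0.0544 with an estimated correlation). Among them were the suberin fatty acid hydroxylase CYP86A1 (comp123706_c0), from 19.9 ± 3.17 to 5.04 ± 1.04 CPM, and the feruloyl transferase ASFT (comp107859_c1), from 25.2 ± 4.05 to 8.07 ± 1.42 CPM.

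Regulators of flowering and ethylene genes fell, and both calls held with an estimated correlation (adjusted p = 0.0427 for each). Of 28 flowering regulators, 16 fell and none rose, the same adjusted over the list alone, with a median of -0.35. The FLC-related gene matched to MAF1 (comp113091_c0) fell from 76.5 ± 5.75 to 19.4 ± 5.35 CPM, and the VRN1-matched gene (comp102529_c0) from 144 ± 17.2 to 49.2 ± 1.15 CPM. Of 22 ethylene genes, 13 fell and 2 rose, including lower levels of the receptor EIN4 (comp132262_c0, log2 fold change -1.01, SE 0.08) and of the response factor RAP2.12 (comp108705_c0, log2 fold change -1.52, SE 0.11). The 23 genes that the deposited annotation ties to ethylene, a set chosen after the values were seen, did not pass the set test here (10 fell and 4 rose, adjusted p = 0.233, and adjusted p = 0.425 with an estimated correlation). Of 26 jasmonate genes, 12 fell and 3 rose (adjusted p = 0.0319, and adjusted p = 0.247 with an estimated correlation), with the repressors JAZ10 (comp126879_c0) and JAZ12 (comp121170_c0) at log2 fold changes of -1.48 and -0.95. This jasmonate call was also lost without paradormant replicate 4 (adjusted p = 0.059), with library size only (adjusted p = 0.0579) and with 1 gene per Arabidopsis identifier (adjusted p = 0.29). The counts for these lists were the same adjusted over the list alone.

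Genes of abscisic acid, the hormone most often tied to bud and seed dormancy, went several ways. The more abundant of 2 tested genes matched to NCED3, for the rate-limiting step of its synthesis (comp131940_c0), fell from 20.1 ± 4.09 to 8.96 ± 1.99 CPM. The CYP707A1-matched gene for its breakdown (comp120931_c0) fell from 94.8 ± 45 to 19.7 ± 7.13 CPM. Of 15 synthesis genes 2 rose and 8 fell, and of 20 signalling genes 5 rose and 6 fell, neither past the set test. The signalling list had a median of -0.12 and a mean of 0.45. The breakdown list had 2 measured genes, too few for a set test, and 1 fell, or 1 fell and 1 rose adjusted over the list alone. The more abundant of 2 tested galactinol synthase genes (comp127913_c0, 0.74 of its reads on that match), at 15.1 ± 10.0 and 15.7 ± 2.45 CPM, did not pass the test (adjusted p = 0.924 in edgeR). Nor did the DRM1-matched gene (comp136283_c0), at 1960 ± 479 and 1910 ± 132 CPM (adjusted p = 0.819 in edgeR). The most abundant of 4 tested genes matched to the D-type cyclin CYCD3 (comp102025_c0) fell by 0.48 (SE 0.09) on the log2 scale. The gene for EPSPS, the target of glyphosate (comp123652_c0), fell by 0.35 (SE 0.08).

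The genes named for the size of their rise, 1 per protein match, included a late embryogenesis abundant protein (comp102477_c0), from 1.72 ± 0.631 to 192 ± 61.5 CPM, and another of that class (comp112460_c0), from 6.46 ± 0.711 to 335 ± 33.6 CPM. A beta-amylase matched to the starch-degrading BAM3 (comp135393_c0) rose from 1.57 ± 0.724 to 56.8 ± 33.0 CPM. An abscisic acid receptor of the PYL class (comp101142_c0) had a ratio of 54.3 (95% counting interval 18.2 to 266), and a protein annotated only as catalytic (comp130822_c0) a ratio of 94.1 (25.6 to 783), each with 3 or fewer reads in the paradormant state. Those named for the size of their fall included a gene matched to the ricin B chain (comp97834_c0), from 150 ± 60.2 to 1.05 ± 1.07 CPM, a carbonic anhydrase (comp118736_c0), from 36.3 ± 21.7 to 0.534 ± 0.896 CPM, and a heat shock protein of the HSP90 class (comp135518_c0), from 232 ± 191 to 3.91 ± 0.942 CPM. A senescence-linked cysteine protease (comp110242_c1) fell from 51.6 ± 12.0 to 0.918 ± 1.34 CPM and a cytochrome P450 (comp114003_c0) from 51.1 ± 18.2 to 0.967 ± 0.928 CPM. Single libraries moved the log2 fold changes of these 5 genes: from -7.08 to -7.94 for the ricin match without endodormant replicate 3, from -6.07 to -8.15 for the carbonic anhydrase without endodormant replicate 1 and from -5.88 to -5.28 for HSP90 without paradormant replicate 4. The protease went from -5.75 to -7.33 without endodormant replicate 3 and the cytochrome P450 from -5.73 to -6.44 without endodormant replicate 1.

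In all, 9496 of 19394 genes changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4792 higher and 4704 lower in endodormant buds, and 2502 of them changed at least 2-fold. With library size as the only scaling, 3524 were higher and 6599 lower (34.8% higher against 50.5%), and the median of all genes was -0.16 on the log2 scale, so directions of small changes against paradormant buds are relative to that shift. Isoforms in place of genes gave 5142 changed of 36325 tested, 3097 higher and 2045 lower (60.2% higher).

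Cell cycle genes (3 rose and 4 fell of 29), DNA replication genes (4 and 5 of 24), meristem identity genes (0 and 7 of 19) and histones (1 and 5 of 20) did not pass the set test in this comparison. Nor did starch synthesis (10 and 2 of 15), starch degradation (9 and 3 of 21), and sucrose, raffinose and trehalose metabolism (5 and 7 of 27). It was the same for dehydrins and late embryogenesis abundant proteins (3 and 1 of 7), photoreceptors (8 and 2 of 16), chromatin regulators (6 and 14 of 40) and heat shock proteins (9 and 16 of 56). Auxin (11 and 10 of 43), cytokinin (6 and 10 of 22), gibberellin breakdown (1 and 1 of 3) and sugar starvation genes (0 and 1 of 3) did not pass it. Markers of phloem (4 rose and 1 fell of 9), of xylem and secondary walls (0 and 4 of 7) and of epidermis and cuticle (5 and 1 of 13) did not pass it either. Medians of the auxin, epidermis and dehydrin lists, at 0.04, 0.07 and 0.06, turned to -0.10, -0.07 and -0.08 with library size only. Adjusted over the list alone, these counts were the same except for cell cycle genes (3 and 3) and histones (1 and 2). Starch synthesis passed the set test without paradormant replicate 2, endodormant replicate 1 or 2, or ecodormant replicate 2 (adjusted p = 0.0254, 0.0322, 0.0297 and 0.0449), and with 1 gene per Arabidopsis identifier (adjusted p = 0.0274). Dehydrins and late embryogenesis abundant proteins passed it without paradormant replicate 2, endodormant replicate 2 or 4, or ecodormant replicate 2 (adjusted p = 0.0358, 0.0366, 0.0478 and 0.0449). FT, the mobile flowering signal, was the match of 8 assembly genes that had 0 counts in the 12 libraries, and AGL24, BRC1 and CCA1 were the chosen match of no assembly gene.

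The second comparison asked what changed as endodormant buds became ecodormant in extended cold. The DAM2-matched gene rose again, from 28.1 ± 6.38 to 153 ± 4.97 CPM (log2 fold change 2.44, SE 0.12, adjusted p = 3.23e-14 in edgeR), and the BAM3-matched beta-amylase from 56.8 ± 33.0 to 561 ± 113 CPM. Genes of flavonoid synthesis, jasmonate, DNA replication and suberin fell, and these 4 set calls held with an estimated correlation. The CBF1-matched gene fell from 103 ± 15.9 to 26.5 ± 4.93 CPM. The named ERD10-matched dehydrin, at 1610 ± 136 and 1660 ± 179 CPM, did not pass the test (adjusted p = 0.753 in edgeR).

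Of 31 phenylpropanoid and flavonoid genes, 25 fell and 1 rose, the same adjusted over the list alone, with a median of -2.45 (set test adjusted p = 4.15e-11, and adjusted p = 0.0245 with an estimated correlation). Chalcone synthase (comp111251_c1), the entry enzyme of flavonoid synthesis, fell from 246 ± 12.3 to 13.6 ± 2.37 CPM (log2 fold change -4.18, SE 0.10), and flavonoid 3'-hydroxylase (comp104372_c0) from 367 ± 25.5 to 30.2 ± 1.29 CPM (log2 fold change -3.6, SE 0.09). Of 26 jasmonate genes, 21 fell and 1 rose (22 and 1 adjusted over the list alone; adjusted p = 1.88e-07, and adjusted p = 0.0245 with an estimated correlation). Among these, the transcription factor MYC2 (comp135828_c0) fell from 46.1 ± 7.03 to 7.19 ± 1.74 CPM and the lipoxygenase LOX2 (comp134791_c1), an early enzyme of jasmonate synthesis, from 28.7 ± 6.13 to 2.27 ± 0.958 CPM.

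Genes of cell division fell at this step. Of 24 DNA replication genes, 19 fell and 3 rose, the same adjusted over the list alone, with a median of -1.94 (adjusted p = 2.15e-06, and adjusted p = 0.0245 with an estimated correlation). The replication licensing factor MCM3 (comp136441_c1) fell from 26.7 ± 2.57 to 1.65 ± 0.419 CPM and the ribonucleotide reductase subunit TSO2 (comp127087_c0) from 33.2 ± 4.2 to 4.39 ± 0.834 CPM. Of 29 cell cycle genes, 19 fell and 3 rose (19 and 4 adjusted over the list alone; adjusted p = 0.000441, and adjusted p = 0.0852 with an estimated correlation). The plant-specific mitotic kinases CDKB2;2 (comp100223_c0) and CDKB1;2 (comp97692_c0) fell from 31.1 ± 3.6 to 0.436 ± 0.385 CPM and from 20.2 ± 3.33 to 0.675 ± 0.383 CPM. The named CYCD3-matched gene (comp102025_c0), 1 of 4 tested, fell from 37.9 ± 2.66 to 10.8 ± 1.5 CPM. Of 20 histone genes, 12 fell and 2 rose (adjusted p = 0.00198, and adjusted p = 0.139 with an estimated correlation), including H2A genes with log2 fold changes of -2.43 (comp105365_c0, SE 0.15) and -5.49 (comp93890_c0, SE 0.45). Of 23 expansins and xyloglucan enzymes, which loosen cell walls, 16 fell and 2 rose (adjusted p = 0.000277, and adjusted p = 0.0852 with an estimated correlation). Expansin-A4 (comp131166_c0) was down from 114 ± 11.7 to 24.4 ± 3.96 CPM and a xyloglucan endotransglycosylase (comp120790_c0) from 77.1 ± 12.2 to 15.9 ± 3.62 CPM. Histone and expansin counts were the same adjusted over the list alone.

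Photosynthesis genes fell after their earlier rise, 34 of 39 lower and none higher, with a median of -0.88 (adjusted p = 5.19e-10, and adjusted p = 0.197 with an estimated correlation). The light-harvesting proteins LHCB3 (comp106911_c0) and LHCA4 (comp113959_c0) fell from 81.7 ± 9.67 to 16.2 ± 4.61 CPM and from 103 ± 14.5 to 29.8 ± 3.27 CPM. In the latter gene, the LHCA4 match held 0.59 of the reads. Several tissue markers fell with these groups. All 5 suberin and periderm markers fell, with a median of -3.75 (adjusted p = 0.000816, and adjusted p = 0.0432 with an estimated correlation), as did all 7 xylem and secondary wall markers, with a median of -2.13 (adjusted p = 0.00198, and adjusted p = 0.0993 with an estimated correlation). The xylem protease XCP1 (comp98765_c0) went from 24.7 ± 2.45 to 5.6 ± 2.15 CPM and the xylan synthesis enzyme FRA8 (comp130200_c0) from 31.0 ± 5.51 to 13.8 ± 1.3 CPM. Of 13 epidermis and cuticle markers 9 fell and none rose (10 adjusted over the list alone; adjusted p = 0.000816, and adjusted p = 0.139 with an estimated correlation), with log2 fold changes of -1.67 (SE 0.12) for the wax enzyme CER6 (comp131747_c0) and -1.52 (SE 0.09) for the cutin enzyme DCR (comp128132_c0). Phloem markers went both ways, 3 higher and 5 lower of 9.

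Circadian clock genes rose further, 15 of 21 higher and 1 lower (adjusted p = 0.00746, and adjusted p = 0.0852 with an estimated correlation). Of 80 transposon-related genes, 31 rose and 11 fell (adjusted p = 0.00667, and adjusted p = 0.139 with an estimated correlation). The shikimate pathway (7 of 12 fell) and branching and strigolactone genes (5 of 11) fell with the preset correlation and lost the call with an estimated correlation (adjusted p = 0.0852 and adjusted p = 0.145). So did starch synthesis (11 of 15, with 3 that rose, adjusted p = 0.299), starch degradation (14 of 21, with 4 that rose, adjusted p = 0.269) and gibberellin synthesis (6 of 9, adjusted p = 0.191). Adjusted over the list alone, 8 shikimate and 15 starch degradation genes fell, and the other counts of these lists, clock and transposon-related genes included, were the same. With 1 gene per Arabidopsis identifier the calls of branching (adjusted p = 0.0697), starch synthesis (adjusted p = 0.065), starch degradation (adjusted p = 0.207) and gibberellin synthesis (adjusted p = 0.117) were lost. Leaving out any library other than ecodormant replicates 1, 3 and 4 also ended the starch degradation call (adjusted p from 0.0317 to 0.0827 over all 12). Cytosolic ribosomal proteins, with 6 higher and 34 lower of 99 (5 and 33 adjusted over the list alone), did not pass the set test (adjusted p = 0.0998). They did without paradormant replicate 1, endodormant replicate 3 or 4, or ecodormant replicate 1 (adjusted p = 0.048, 0.0317, 0.0434 and 0.0381). Abscisic acid signalling, with 9 higher and 6 lower of 20 (11 and 6 adjusted over the list alone), had an adjusted p of 0.05 and did not pass. It did without any library but ecodormant replicate 3 (adjusted p = 0.0194 to 0.0468). Cytokinin genes, 3 higher and 11 lower of 22, the same adjusted over the list alone, did not pass either (adjusted p = 0.0586). They did without any library but endodormant replicates 1 and 3 (adjusted p = 0.0258 to 0.0492).

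Among single genes of the fixed set, the DRM1-matched gene rose from 1910 ± 132 to 3360 ± 169 CPM. The named gene of galactinol synthase, which starts raffinose synthesis, 1 of 2 tested, rose from 15.7 ± 2.45 to 54.8 ± 10.7 CPM. The named NCED3-matched gene, 1 of 2 tested, fell again, to 2.97 ± 1.4 CPM. The CYP707A1-matched gene, at 29.1 ± 2.91 CPM, did not pass the test (adjusted p = 0.0876 in edgeR). It did without paradormant replicate 4 (adjusted p = 0.00452) or endodormant replicate 3 (adjusted p = 0.0173). A CYP707A4-matched gene (comp111436_c2) fell from 14.7 ± 1.25 to 2.57 ± 0.853 CPM. The LHY-matched gene rose by 0.35 (SE 0.09) on the log2 scale. The abundant SVP-matched gene (log2 fold change -0.12, SE 0.07, adjusted p = 0.140) and EPSPS (-0.20, SE 0.09, adjusted p = 0.0553) did not pass the edgeR test. EPSPS did with 1 library left out, for each paradormant library, endodormant replicate 3 and ecodormant replicate 2 (adjusted p = 0.0274 to 0.0472) and with library size only (adjusted p = 0.0415).

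The genes named for the size of their rise included a tonoplast dicarboxylate transporter (comp109911_c1), from 9.04 ± 2.91 to 228 ± 59.8 CPM, a bZIP protein matched to the light-inducible CPRF-2 (comp121421_c0), from 2.02 ± 0.578 to 55.3 ± 8.90 CPM, and a ribonuclease H-fold protein (comp111431_c0), from 1.38 ± 0.773 to 44.1 ± 5.81 CPM. An H-type thioredoxin (comp104864_c0) rose from 0.710 ± 0.538 to 22.3 ± 4.82 CPM and a second beta-amylase (comp101358_c0) from 0.649 ± 0.436 to 10.8 ± 1.87 CPM. Of those named for the size of their fall, 3 had no reads in any ecodormant library, so that the fold is a bound set by 3 counts over the group. A ribosome-inactivating protein matched to Euserratin 1 (comp138392_c0) was at least 69.0-fold lower than its endodormant 15.4 ± 3.71 CPM, a phosphoglycerate dehydrogenase (comp109866_c0) at least 20.2-fold lower and a pectate lyase (comp121916_c0) at least 19.6-fold lower. A protein annotated only as transferase (comp109162_c0), with 1 ecodormant read, was lower by a ratio of 144 (95% counting interval 25.5 to 5740). That read was in replicate 1, without which the gene was at least 37.3-fold lower.

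In all, 10184 of 19394 genes changed in this comparison (edgeR, Benjamini-Hochberg adjusted), 4896 higher and 5288 lower in ecodormant buds, and of the 3304 that changed at least 2-fold, 1103 were higher and 2201 lower. Isoforms in place of genes gave 5761 changed of 36325 tested, 2232 higher and 3529 lower (38.7% higher against 48.1%).

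**Figure D2:**
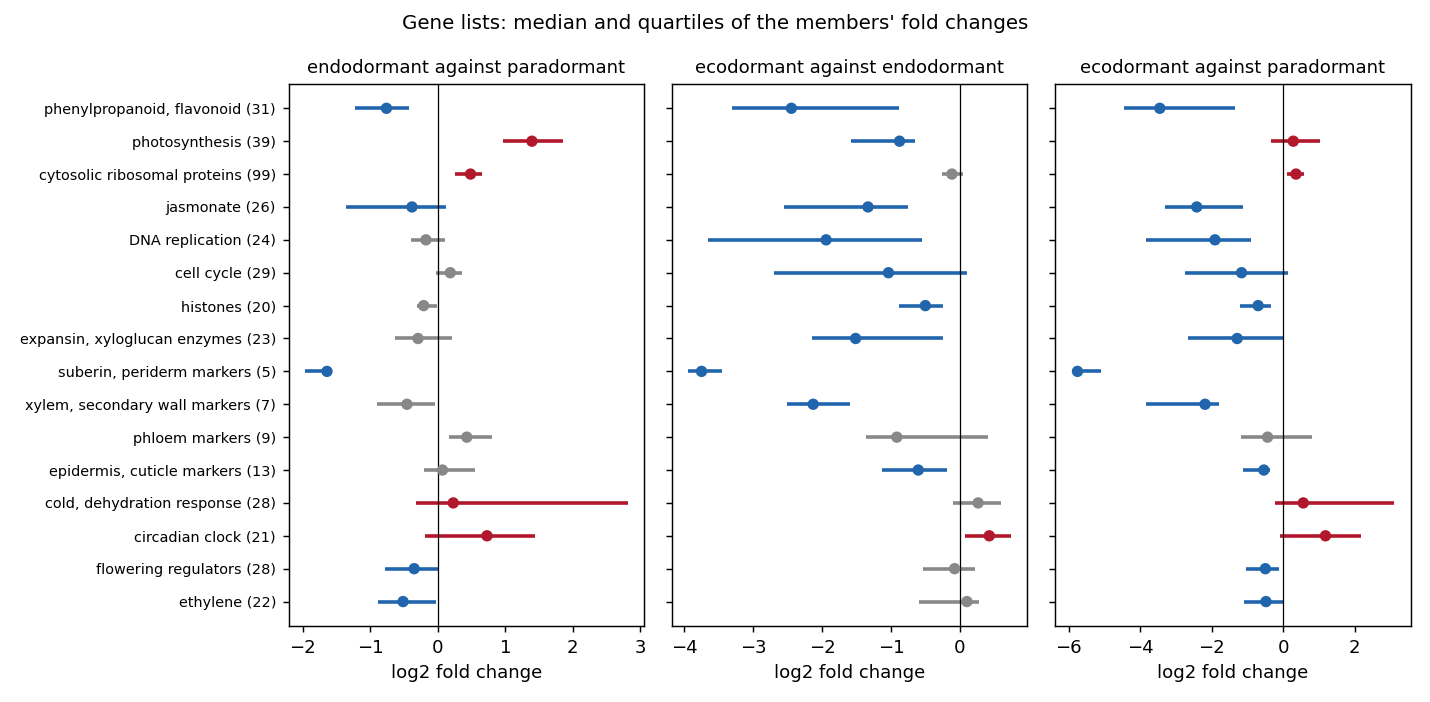
Points are the median and lines the quartiles of the log2 fold changes of the measured genes, whose number is in parentheses, for a selection of the lists in the 3 comparisons. Red and blue mark lists higher and lower by the set test with the preset correlation (adjusted p under 0.05), and grey marks the rest. Photosynthesis moved up by a median of 1.4 and then down by 0.88, while suberin and flavonoid lists fell at both steps. With another scaling the epidermis median (endodormant against paradormant) changes sign. So do medians of lists not drawn: auxin and dehydrin genes (endodormant against paradormant), heat shock proteins (both ecodormant comparisons) and sugar starvation and transposon genes (ecodormant against paradormant).

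The third comparison set the ends of the time course against each other. Ecodormant buds had far more DAM2-matched transcript than paradormant buds, 153 ± 4.97 against 1.96 ± 0.964 CPM (log2 fold change 6.29, SE 0.18, adjusted p = 3.55e-19 in edgeR), and more of the second SVP-matched gene (log2 fold change 0.65, SE 0.07). The BAM3-matched beta-amylase was higher by 8.47 (SE 0.37) on the log2 scale, and flavonoid and jasmonate genes were lower as groups. Of 31 phenylpropanoid and flavonoid genes, 27 were lower and 2 higher, with a median of -3.45 (adjusted p = 2.12e-10, and adjusted p = 0.0243 with an estimated correlation). The gene with the Arabidopsis match dihydroflavonol reductase (comp90689_c0, protein match cinnamoyl-CoA reductase) fell from 605 ± 60.5 to 10.8 ± 2.61 CPM (log2 fold change -5.81, SE 0.13). Flavonoid 3'-hydroxylase fell from 545 ± 41.0 to 30.2 ± 1.29 CPM. Of 26 jasmonate genes, 24 fell and 2 rose (adjusted p = 2.37e-07, and adjusted p = 0.0243 with an estimated correlation), with JAZ10 down from 89.9 ± 9.98 to 12.7 ± 1.98 CPM and JAZ12 from 230 ± 20.2 to 53.7 ± 2.68 CPM. Counts for both lists were the same adjusted over the list alone.

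All 5 suberin and periderm markers were lower (median -5.75, adjusted p = 0.000626, and adjusted p = 0.0443 with an estimated correlation), and CYP86A1 stood at 0.315 ± 0.365 CPM. All 7 xylem markers were lower (median -2.18, adjusted p = 0.00295, and adjusted p = 0.0851 with an estimated correlation), among them the protease XCP2 (comp99949_c0), from 7.81 ± 2.68 to 0.509 ± 0.254 CPM. Of 9 phloem markers, 3 were higher and 4 lower. DNA replication genes (19 of 24 lower, 4 higher, adjusted p = 0.000426, and adjusted p = 0.0572 with an estimated correlation) and histones (13 of 20 lower, none higher, adjusted p = 0.00174, and adjusted p = 0.0990 with an estimated correlation) were lower. MCM3 was down from 40.4 ± 11.8 to 1.65 ± 0.419 CPM and a histone H4 gene (comp81424_c1) from 80.6 ± 11.7 to 29.6 ± 1.53 CPM. Expansins and xyloglucan enzymes (15 of 23 lower, 2 higher) had an adjusted p of 0.00335, and an adjusted p = 0.105 with an estimated correlation.

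Cytosolic ribosomal proteins (66 of 99 higher, 9 lower; 68 and 9 adjusted over the list alone) and circadian clock genes (14 of 21 higher, 4 lower) were higher. Their adjusted p were 6.7e-06 and 0.00415, and adjusted p = 0.419 and 0.0572 with an estimated correlation. A gene with the protein match 60S ribosomal protein L34 (comp128076_c0, Arabidopsis match AT5G39785) rose from 6.52 ± 1.97 to 52.8 ± 8.37 CPM. Its place on the list rests on the words of the protein match. Its log2 fold change of 3.00 was far above the list median of 0.36, so it does not stand for the list. The clock activator RVE8 (comp115633_c0) rose from 36.4 ± 5.75 to 267 ± 21.4 CPM. Flowering regulators were lower (15 of 28, with 3 higher, adjusted p = 0.00474, and adjusted p = 0.0572 with an estimated correlation), with the MAF1-matched gene down from 76.5 ± 5.75 to 8.16 ± 0.840 CPM. Cold and dehydration genes were higher (17 of 28, with 6 lower, adjusted p = 0.00568, and adjusted p = 0.171 with an estimated correlation). Photosynthesis genes stood between, 22 higher and 10 lower of 39 (adjusted p = 0.0313, and adjusted p = 0.633 with an estimated correlation). Without paradormant replicate 2 or 4, or ecodormant replicate 4, their call was lost (adjusted p = 0.0929, 0.0524 and 0.0751). Except for ribosomal proteins, counts of the lists in this and the preceding paragraph were the same adjusted over the list alone.

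Further lists were lower with the preset correlation and lost the call with an estimated one. They were cell cycle (18 of 29 lower, adjusted p = 0.105 with an estimated correlation), shikimate pathway (9 of 12, adjusted p = 0.0890) and branching and strigolactone (8 of 11, adjusted p = 0.103). Among hormones they were ethylene (16 of 22, adjusted p = 0.0581), gibberellin signalling (7 of 12, adjusted p = 0.0799), gibberellin synthesis (7 of 9, adjusted p = 0.171) and cytokinin (15 of 22, adjusted p = 0.0851). The others were meristem identity (10 of 19, adjusted p = 0.0851) and epidermis and cuticle (10 of 13, adjusted p = 0.261). The cytokinin call was also lost without ecodormant replicate 2 or 4 (adjusted p = 0.0519 and 0.0529) and with 1 gene per Arabidopsis identifier (adjusted p = 0.0901), and that of gibberellin synthesis with library size only (adjusted p = 0.0535) and with 1 gene per identifier (adjusted p = 0.209). The numbers of lower genes were the same adjusted over the list alone. Not past the set test were abscisic acid signalling (9 higher and 4 lower of 20, adjusted p = 0.0543), abscisic acid synthesis (1 and 9 of 15, adjusted p = 0.057) and dehydrins and late embryogenesis abundant proteins (4 and 1 of 7, adjusted p = 0.0964), the same adjusted over the list alone. Signalling passed without any library but paradormant replicate 4 and ecodormant replicates 3 and 4 (adjusted p = 0.0272 to 0.0443). Synthesis passed without endodormant replicate 1 or ecodormant replicate 1 or 3 (adjusted p = 0.0484, 0.043 and 0.0462). Dehydrins passed without paradormant replicate 2, endodormant replicate 2 or 3, or ecodormant replicate 2 (adjusted p = 0.0403, 0.0441, 0.0494 and 0.0362).

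Of the fixed genes, the named ERD10-matched dehydrin (log2 fold change 2.76, SE 0.11) and the named galactinol synthase gene (1.85, SE 0.25), each 1 of 2 tested, were higher in ecodormant buds. So were the CBF1-matched gene (1.85, SE 0.18), LHY (0.76, SE 0.09) and DRM1 (0.78, SE 0.11). The named NCED3-matched gene, 1 of 2 tested (-2.74, SE 0.25), and CYP707A1 (-1.70, SE 0.22) were lower. The named CYCD3-matched gene, 1 of 4 tested (-2.27, SE 0.12), and EPSPS (-0.55, SE 0.08) were also lower. The genes named for the size of their rise beside BAM3 were the second beta-amylase, at least 58.4-fold above paradormant libraries without a read, a late embryogenesis abundant protein (comp102477_c0, log2 fold change 7.51, SE 0.26), the ribonuclease H-fold protein (6.56, SE 0.29, and 7.32 without paradormant replicate 1) and a protein annotated only as hydrolase (comp121595_c0), with a ratio of 218 (95% counting interval 38.7 to 8670). Its 1 paradormant read was in replicate 3, without which it was at least 54.5-fold higher. Of the genes named for the size of their fall, 4 had no read in the ecodormant libraries: the carbonic anhydrase (at least 159-fold), the Euserratin 1 match (at least 99.2-fold), the phosphoglycerate dehydrogenase (at least 65.3-fold) and a Euserratin 2 match (comp93095_c0, at least 52.8-fold). The ricin B chain match (comp97834_c0), not named in this comparison by the rule because another gene with a smaller p shares its match, fell further, by at least 665-fold. A gene matched to allene oxide synthase, an enzyme of jasmonate synthesis (comp115476_c0, 0.79 of its reads on that match), fell from 134 ± 29.7 to 0.377 ± 0.299 CPM.

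In all, 12486 genes changed between the ends of the time course (edgeR, Benjamini-Hochberg adjusted), 6133 higher and 6353 lower in ecodormant buds, and 5240 changed at least 2-fold. With library size as the only scaling, 4791 were higher and 7701 lower (38.4% higher against 49.1%), with a median of all genes of -0.16 on the log2 scale.

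**Figure D3:**
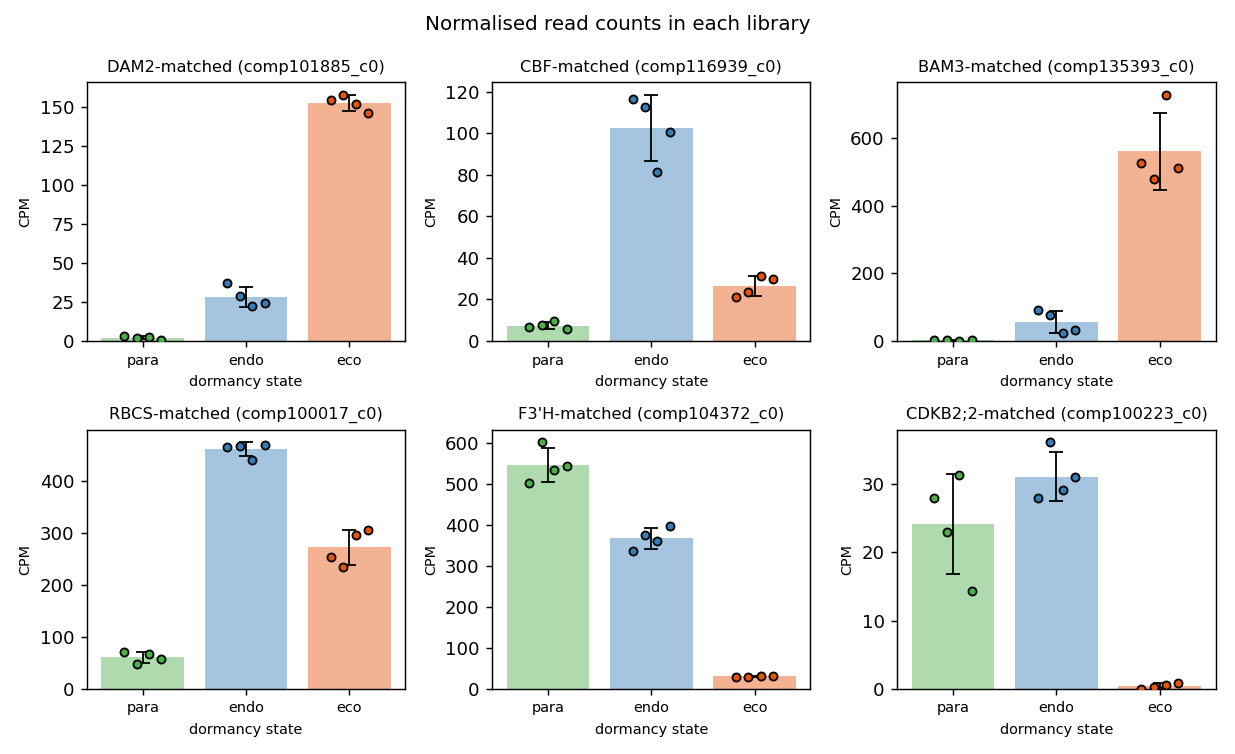
Bars are the mean and error bars the SD of CPM in the 4 libraries of each state (para, endo, eco), and points are single libraries, for 6 genes named by their match. DAM2 and BAM3 matches rise at each step to 153 and 561 CPM, CBF and the Rubisco small subunit peak in endodormant buds at 103 and 460 CPM, and flavonoid 3'-hydroxylase and CDKB2;2 fall to 30.2 and 0.436 CPM in ecodormant buds.

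Taking both transitions, 1496 genes rose into endodormancy and then fell, 1211 fell and then rose, 1367 rose at both steps and 1418 fell at both. Independent lists of these sizes would share 1307, 1188, 1210 and 1283 genes. That reference takes every gene as equally easy to call, though genes with more counts pass more readily at both steps. An excess over it can thus arise in every class without shared regulation. With library size as the only scaling the counts of these classes were 1143, 1705, 1021 and 1906, against 974, 1642, 877 and 1823 for independent lists. Which of the 2 reversed classes was larger thus turned with the scaling. At 2-fold or more in both steps, 170 genes rose then fell, against 137 for independent lists, and 157 fell then rose, against 74. By the same measure 208 rose in both, against 69, and 366 fell in both, against 147. The transitions share the endodormant libraries, which alone pushes their fold changes apart: unchanged groups simulated from these libraries had a mean covariance of -0.02 between the transitions, and the observed covariance was 0.096, a difference of 0.116. With separate endodormant libraries for each step, averaged over the 6 ways to halve them, 1835.5 genes reversed, against 1691 for independent lists, and 2112 moved the same way at both steps, against 1683, with a covariance of 0.116. The 6 ways disagreed, with 1781 to 1946 genes reversed, 1785 to 2586 the same way and a covariance of 0.055 to 0.186. With endodormant replicates 3 and 4 in the first step, more genes reversed (1946) than moved the same way (1785). With replicates 1 and 2 there, 1818 reversed, fewer than the 1910 of independent lists. DESeq2, over 30303 genes, gave 1980 reversed, against 1197 for independent lists, and 1979 the same way, against 1190, with a covariance of 0.045.

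The authors' deposited table gives posterior probabilities of differential expression for the same comparisons. At a probability of 0.95 or more it lists 4919 genes for endodormant against paradormant, 5188 for ecodormant against endodormant and 8150 for ecodormant against paradormant. Of those that edgeR tested, 99.9%, 99.1% and 99.9% were also called by edgeR. In the other direction, 49.4%, 48.3% and 59.2% of edgeR's calls reached that probability in the authors' deposited table.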

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

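Tests of tissue share and of scaling were chosen after the results were seen; those of the shared libraries, the detection floor and the splits were written before. In 279 groups of 4 libraries, for 89 genes and 4 library measures, 19 held a library far from the other 3, where chance, at about 1 in 20 groups, gives 13.9. Some of these groups had reads in 1 library and 0 in the other 3, which is flagged by construction. The 19 are therefore no evidence of more outliers than chance gives. In paradormant buds, the CYP707A1 match (comp120931_c0) was at 162 CPM in replicate 4 against 66.1 to 79.9 in the others, comp109162_c0 at 7.46 in replicate 1 against 0.739 to 1.68, the L34 match (comp128076_c0) at 3.59 in replicate 1 against 7.20 to 7.90, comp121595_c0 at 0.246 in replicate 3 against 0, comp100007_c0 at 0.239 in replicate 4 against 0, comp89786_c0 at 15.1 in replicate 2 against 18.5 to 19.1, and the PYL match (comp101142_c0) at 0 in replicate 4 against 0.232 to 0.276. In endodormant buds, comp120931_c0 was at 30.3 CPM in replicate 3 against 14.9 to 17.1, the carbonic anhydrase (comp118736_c0) at 1.86 in replicate 1 against 0 to 0.272, the Rubisco small subunit (comp100017_c0) at 440 in replicate 3 against 464 to 469, the second beta-amylase (comp101358_c0) at 0 in replicate 4 against 0.815 to 0.932, the ERD10 match (comp116004_c0) at 1410 in replicate 3 against 1660 to 1690, and the DRM1 match (comp136283_c0) at 1720 in replicate 2 against 1960 to 1990. In ecodormant buds, comp101358_c0 was at 13.6 CPM in replicate 3 against 9.51 to 10.2, comp109162_c0 and comp89786_c0 each at 0.331 in replicate 1 against 0, comp66355_c0 at 0.299 in replicate 4 against 0, a ribosome-inactivating protein match (comp102207_c0) at 3.64 in replicate 1 against 0.839 to 1.13, and the xyloglucan enzyme (comp120790_c0) at 10.5 in replicate 3 against 17.5 to 17.9.

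Photosynthesis genes were highest in endodormant buds. The choice of scaling does not account for this, since the list median kept its direction with a size of at least 0.86 on the log2 scale over 4 scalings and both steps. Chance values of the shared endodormant libraries do not either: with separate libraries for each step, 92.3% to 94.9% of the genes still rose and then fell. A larger share of green tissue in the endodormant samples may also contribute and was not settled, because epidermis and cuticle markers had a median of 0.069 there (-0.07 with library size only) and the bud has an epidermis of its own. A response of the bud to the ramp in temperature and light remains an open hypothesis. States cannot be separated from temperature, plant age and time of sampling in this design. Day length cannot be separated from the paradormant state, but it was 8 h for both endodormant and ecodormant plants.

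Cell cycle and DNA replication genes were lower in ecodormant than in endodormant buds. A smaller share of meristem tissue was not settled as a cause. Meristem identity genes had a median of -0.35 with quartiles of -1.20 and 0.28, against a median of -1.24 for the 53 genes of the pattern. These markers fell less at the median, but they went both ways and their lower quartile all but reached the pattern's median, so they cannot decide. Counts near the detection floor could not be excluded for all members, since the 26 abundant ones had a median of -0.80 with an upper quartile of 0.07. Lower division in the cold-treated buds is a hypothesis that these libraries cannot separate from meristem share, the temperature at harvest or the age of the plants.

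Flavonoid genes were lower in ecodormant than in paradormant buds, with a median of -3.45. A smaller share of epidermis was argued against as the whole cause by a median of -0.54 of its markers (lower quartile -1.11). That holds only as far as their expression within the epidermis did not change. Phloem markers had a median of -0.44 with quartiles of -1.18 and 0.81. They went both ways, so they cannot decide on a smaller share of phloem. A smaller share of xylem remains open, since its markers had a median of -2.18 and a lower quartile of -3.84 that reaches past the flavonoid median. So does a smaller share of periderm: its markers fell even further, with a median of -5.75, and tissue share cannot be told apart from expression within the tissue. A change of flavonoid synthesis within the bud, with state, temperature, light or plant age, stays a hypothesis beside them.

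For each of the 3 comparisons, the 35 ways to part the 8 libraries into 4 and 4 were run, and only the real 1 of the 35 called as many genes. The real counts were 9496, 10184 and 12486, and the highest of the other splits called 0. Those splits mix both states, which widens the spread within each group, so few calls are likely there once the states differ. A share of 1 in 35 is the smallest this test can give, so a chance arrangement of the libraries is unlikely but not excluded.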

How the results depend on the processing

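All alternatives here were planned. Of the 262 tests of single genes considered for naming, 256 kept direction and side of the threshold in every alternative, 1 lost its call in some alternative, 2 gained one and 3 changed sign, none of these 3 called in the test as reported. Counts of changed genes stayed within 1.5 times under DESeq2 (8081, 9007 and 12987 in the order of the report), other scalings and filters. They were lower with isoforms (5142 and 5761 in the first and second comparison) and at 2-fold or more (2502, 3304 and 5240), where fewer genes can pass by construction. Leaving out 1 library gave 8674 to 9609, 9543 to 10686 and 12103 to 12872. With an estimated correlation, 2, 4 and 3 lists were called. Reversed genes numbered 327 at 2-fold or more in both steps. Replicate numbers as a whole did not pair the libraries (r of deviations -0.039 to 0.042 for equal and -0.065 to 0.052 for other numbers). Of the 12 libraries, 3 agreed best with their own number in both other states, all of replicate 2 (r of 0.037 to 0.042 between them). With the replicate block 9394, 10087 and 12369 genes changed. With that block the cytokinin list, ecodormant against endodormant, passed the set test (adjusted p = 0.0453 against 0.0586).

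Lists whose direction in the set test turned (medians that turned are given in the report) had no call as reported, and the cause was not tested. With 1 gene per Arabidopsis identifier these were, for endodormant against paradormant, abscisic acid signalling (adjusted p = 0.857), auxin (0.789), sucrose metabolism (0.789) and DNA replication (0.974), for ecodormant against endodormant chromatin regulators (0.67), and for ecodormant against paradormant starch degradation (0.84), starch synthesis (0.905) and sucrose metabolism (0.905). With library size only they were phloem markers (0.903) and heat shock proteins (0.918), and with the block heat shock proteins (0.98). The named galactinol synthase gene turned to -0.10 with library size only. Over the libraries left out in turn, these adjusted p ran from 0.796 to 0.984 (abscisic acid signalling), 0.656 to 0.965 (auxin), 0.617 to 0.985 (DNA replication), 0.768 to 0.986 (starch degradation), 0.911 to 1 (phloem) and 0.709 to 0.998 (heat shock). Log2 fold changes ran from -0.028 to 0.083 for comp116004_c0 (ecodormant against endodormant), and for endodormant against paradormant from -0.21 to 0.4 for comp127913_c0 and from -0.176 to 0.104 for comp136283_c0.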

Other observations

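The genes, sets and tests in this part were chosen after their values were seen, and no explanation was tested for them. Genes matched to ribosome-inactivating proteins and ricin-like lectins, which in other plants act in defence, were measured in 12 assembly genes. From endodormant to ecodormant buds 9 of them fell and 1 rose, with a median log2 fold change of -2.78 (adjusted p = 0.00215 by camera, and adjusted p = 0.168 with an estimated correlation). The most abundant in paradormant buds, a match to the Nigrin l precursor (comp93118_c0), was at 947 ± 260 CPM (SD, n = 4) there, 63.4 ± 41.0 in endodormant and 3.68 ± 1.88 in ecodormant buds. The ricin B chain match (comp97834_c0) had no read in ecodormant buds, at least 665-fold below its paradormant level of 150 ± 60.2 CPM. A Euserratin 2 match (comp115647_c1) went the other way, from 30.8 ± 3.56 to 450 ± 70.0 and 778 ± 101 CPM.

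Of the 19394 tested genes, 1930 had neither an Arabidopsis nor a protein match, and 844, 1070 and 1106 of them changed in the 3 comparisons. These were 43.7%, 55.4% and 57.3% of them, against 49.5%, 52.2% and 65.2% of the genes with a match. Genes without a match made up 20, 6 and 15 of the 100 largest changes. Among these genes comp105414_c0 rose from 2.3 ± 1.4 to 489 ± 89.3 CPM between paradormant and endodormant buds (log2 fold change 7.72, SE 0.21, edgeR adjusted p = 6.55e-19). The gene comp100007_c0, with 1 and 2 reads in the paradormant and endodormant libraries, was at 44.2 ± 3.64 CPM in ecodormant buds. Genes that the deposited annotation ties to salicylic acid (20 genes, 10 lower and 4 higher, median -0.87) and to jasmonate (60 genes, 28 lower and 12 higher, median -0.40) had an adjusted p = 0.0263 each between endodormant and ecodormant buds, and an adjusted p = 0.168 each with an estimated correlation. The jasmonate set was also lower in ecodormant than in paradormant buds (34 lower and 15 higher, adjusted p = 0.017, and adjusted p = 0.215 with an estimated correlation). These were 3 of 27 tests of 9 such hormone sets, and the other 24 did not pass (adjusted p = 0.0578 to 0.952). Among those were ethylene and jasmonate for endodormant against paradormant buds (adjusted p = 0.233 each). The share of counts in genes whose match is from an animal was 0.073% ± 0.007 in paradormant, 0.030% ± 0.001 in endodormant and 0.038% ± 0.001 in ecodormant libraries, with an exact two-sided permutation p = 0.0286 in each comparison, the smallest that 4 against 4 can give.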
